A study of Mus musculus with 12 samples.

How the data were processed

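Total RNA of whole kidneys was hybridised to Affymetrix mouse gene arrays, 1 array per mouse, 12 in all. Groups and replicate numbers were taken from the sample titles: 4 mutants, 4 heterozygotes and 4 wild-type mice, all female. The labels name a mouse gene 1.0 ST array in the sample descriptions, while the labelling text names the human array of the same series. The probe sets matched mouse genes, so they were read as a mouse array. The description numbers of the samples run group by group. Whether they give the order of processing is not stated, so any effect of that order cannot be told apart from genotype. No scan date or batch was given in the sources used here.

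The authors deposited log2 values per probe set, normalised by RMA in Affymetrix Expression Console 1.2.1, per the submitters' processing notes. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a set by a robust additive model. It compresses differences near background and assumes that most genes do not shift together. These values were used as deposited, without a further step unless an alternative below names one. The table had 35552 probe sets with 0 missing values, and all 12 columns were used.

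Probe sets were named through the platform annotation. Of the 23406 listed there, 21785 had 1 gene symbol and 1621 several, and 12146 probe sets were not listed. Symbols were checked by Entrez identifier against RefSeq gene names of assembly GRCm38.p6, where 21694 matched and 0 changed. The genome build of the probe sets is not given in the sources used here, so no coordinates are printed. Each gene was represented by its brightest probe set on average, which left 19934 genes, 999 of them with several probe sets.

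Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and with data.table, version 1.17.8. A fit of all 3 groups shared 1 estimate of the spread, with 9 residual and 4.408 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the 19934 genes of each comparison. A gene was called at an adjusted p under 0.05. These p-values measure the spread between mice, each on its own array, and the number of arrays limits the precision. For Mmut, Lcn2 and Havcr1 two-sided exact permutation tests were added. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

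The genes named follow a rule fixed before the data were examined. For mutant against wild type these were the 10 largest rises and 10 largest falls among called genes with all 4 arrays of each group apart and a group mean of at least 6, and the 5 largest each way for the other comparisons. To these were added up to 4 called members per list with the largest changes, or the member with the smallest p, and Mmut, Lcn2 and Havcr1 in any case. Unnamed gene models, small RNAs, immunoglobulin and receptor segments and olfactory or vomeronasal receptor genes were counted but not named by the rule.

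Of 40 lists, 23 were gene lists of pathways and 17 held cell type markers. They were written from general knowledge before the data were examined and hold 775 distinct genes, some in several lists. Each was tested with camera at a preset correlation of 0.01 as the main test, with camera at an estimated correlation, and with fry, adjusted over the 40 lists. A count adjusted over the list alone used the members' p-values only.

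The fits were tested on simulated data for mutant against wild type over 19934 genes, with the spread of the real ones. Of 67 genes changed by 0.5 on the log2 scale 64 were recovered, as were all 67 changed by 1 and all 66 changed by 2, and 0 were called in the wrong direction. In that set 20 unchanged genes were called beside the recovered ones, a larger share of false calls than in any further draw. Over 20 further draws that share averaged 4.48% and ranged from 2.45% to 7.44%. A simulated list shifted by 0.3 was called with both settings of camera, and 0 of the unshifted lists were. The simulated genes were drawn independently of each other. These runs therefore do not test the false calls of genes or lists where genes vary together, as they can on real arrays.

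Alternatives chosen before the data were examined were the replicate number as a block, each array left out, genes with a group mean of at least 6, every probe set on its own, the mean of a gene's probe sets, array weights, a trended and robust variance prior, only the groups compared in the fit, centring of array medians, quantile normalisation of the deposited values, a threshold of 1.5-fold and pooled controls. A fit without the 34 genes over 2-fold higher in mutant replicate 3 than on any other array was added after seeing the data. Mutant replicate 2 had 40 such genes and every other array at most 4, and no such fit was made for mutant replicate 2. Probe sets with several or no gene symbols, 13767 in all, were left out of the gene tests and are described in the closing section.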

Results

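Kidney expression was measured on 12 mouse arrays, 1 per female mouse, after 2 months on a high-protein diet. All mice were of the C57BL/6 background and fell into 3 genotype groups of 4. The mutants lacked Mut, the gene of the mitochondrial enzyme methylmalonyl-CoA mutase (current symbol Mmut), and carried a Mut transgene named TgINS-Alb-Mut. The controls were heterozygotes, with 1 intact Mut allele, and wild-type mice. In the genotype labels used here only the mutants have this transgene, so its effects cannot be told apart from loss of the enzyme. Loss of this enzyme gives methylmalonic acidemia, and the comparisons asked which transcripts of the whole kidney differ between the mutants and their controls. The table held 35552 probe sets on a log2 scale, from which 19934 genes were tested. Array medians lay between 7.17 and 7.23, correlations between arrays ranged from 0.982 to 0.995 across probe sets, and 4 arrays per group limit the precision.

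The first principal component held 34.2% of the variance. Mutants scored from -31.0 to -6.13, heterozygotes from 1.27 to 4.08 and wild-type mice from 7.88 to 14.8. Mutant replicate 3 was the array at -31.0 and also scored -15.9 on the second component.

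**Figure D1:**
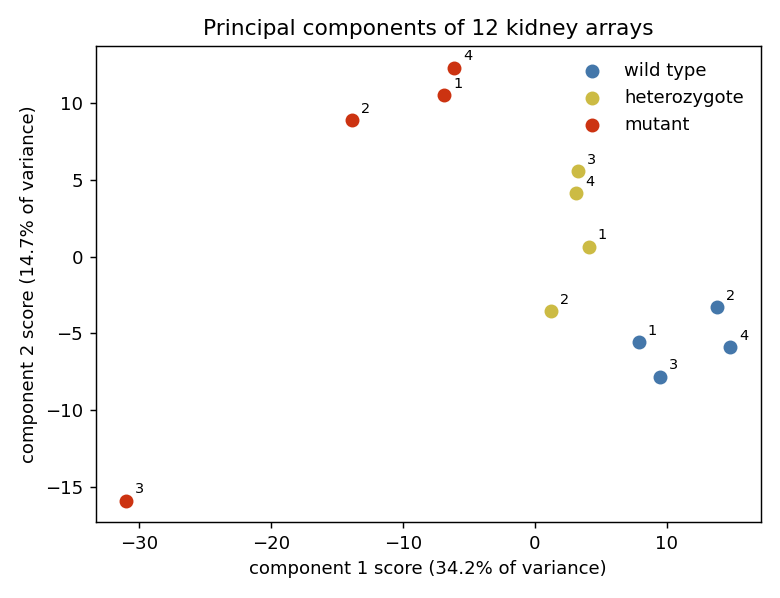
Scores of the 12 arrays on the first and second principal components of 19934 genes, coloured by genotype, with the replicate number beside each point. The groups lie in order of genotype along the first component, and mutant replicate 3 sits apart at -31.0.

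Mmut itself was lowest in the mutants, at 8.35 ± 0.12 on the log2 scale (SD, n = 4), against 9.92 ± 0.04 in heterozygotes and 10.53 ± 0.06 in wild-type mice. The mutant level was 4.52-fold below wild type (log2 fold change -2.18, SE 0.06, adjusted p = 1.4e-10) and 2.95-fold below heterozygotes (adjusted p = 1.14e-08). Heterozygotes were 1.53-fold below wild type (adjusted p = 0.000801). No array of one genotype overlapped another, and the two-sided exact permutation p of each comparison was 0.0286, the smallest that 4 against 4 arrays can give. Where the probes of this gene lie relative to its disrupted part was not determined, nor whether they also read the Mut transgene, so the mutant level and its folds are not a measure of intact transcript of the gene itself. Xist, transcribed from the inactive X chromosome, lay between 12.26 and 12.43 on every array.

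In mutants against wild-type mice, the largest rises included both markers of tubular injury fixed beforehand. Lcn2, which encodes neutrophil gelatinase-associated lipocalin, was 7.73-fold higher (log2 fold change 2.95, SE 0.49, adjusted p = 0.00272), and Havcr1, which encodes kidney injury molecule 1, was 4.13-fold higher (log2 fold change 2.05, SE 0.56, adjusted p = 0.0359). Lcn2 varied widely among mutants, from 8.35 to 11.33, while wild-type arrays held 7.01 to 7.38. Over the alternatives its log2 fold change ran from 2.56 to 3.56. For both genes the exact permutation p was 0.0286. The call of Havcr1 ended without any 1 of 7 arrays, with adjusted p up to 0.097. The fatty acid hydroxylase genes Cyp4a12b and Cyp4a12a rose 7.46-fold and 6.2-fold, and the fatty acid binding protein gene Fabp1 rose 6.97-fold, with single mutants from 8.01 to 11.30. Klk1b22, of the kallikrein family of serine proteases, rose 26.1-fold. Nat8f5, the serine protease inhibitor gene Serpina3n, the monoacylglycerol acyltransferase gene Mogat1 and the neuropeptide Y receptor gene Npy6r rose between 2.71-fold and 4.11-fold. The arrays can confuse close relatives within the Klk1b and Cyp4a families.

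The largest fall among the named genes was that of Akr1c18, which encodes the progesterone-degrading enzyme 20-alpha-hydroxysteroid dehydrogenase, at 29.3-fold below wild type (log2 fold change -4.87, SE 0.38, adjusted p = 1.57e-05). Kap, the kidney androgen-regulated protein gene, was 6.29-fold lower, with mutants from 9.75 to 11.44 against 13.23 to 13.31 in wild-type mice. The transport protein genes Ttr and Alb were 4.93-fold and 3.2-fold lower, and the growth factor gene Igf2 was 4.67-fold lower. Dio1, which encodes a deiodinase that activates thyroid hormone, was 4.05-fold lower. The fatty acid desaturase gene Scd1, the chemokine gene Ccl28 and the organic anion transporter gene Slc22a7 were 3.09-fold, 3.04-fold and 2.87-fold lower. The call of Ccl28 ended without any 1 of 6 arrays, with adjusted p up to 0.0751.

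**Figure D2:**
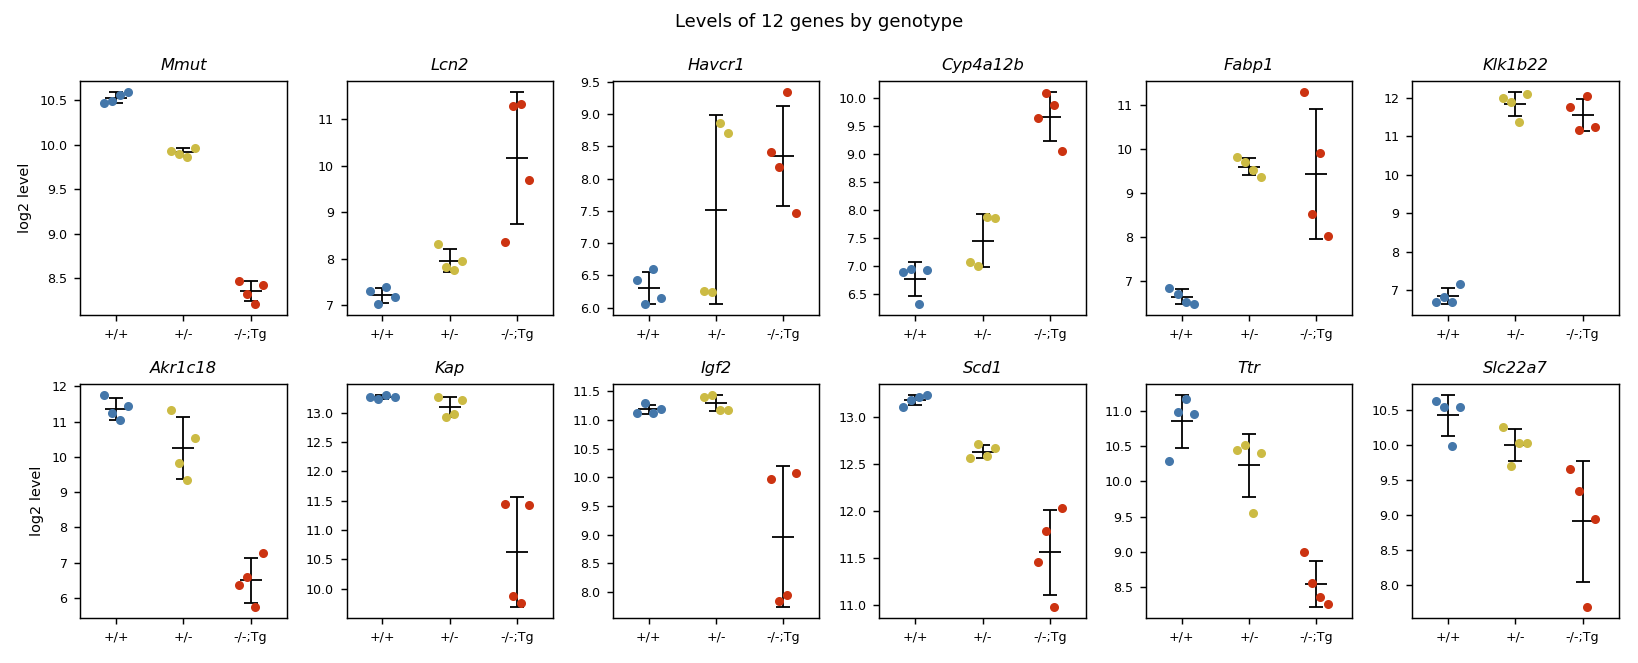
Log2 levels of 12 genes on each array by genotype (+/+ wild type, +/- heterozygote, -/-;Tg mutant), with the group mean and SD as bars (n = 4) and an axis per gene that does not start at 0. Mmut falls from 10.53 to 9.92 to 8.35, and Lcn2 in mutants spreads from 8.35 to 11.33.

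In all, 1925 of the 19934 genes differed between mutant and wild type with limma at an adjusted p under 0.05, of which 591 were higher and 1334 lower in mutants. Most changes were small: 207 of the genes differed by at least 1.5-fold, 81 of them higher and 126 lower. All 4 mutants lay apart from all 4 wild-type arrays in 14.7% of genes, against 2.86% by chance. The share was also above chance in the other comparisons. It was 9.69% for mutant against heterozygote and 8.44% for heterozygote against wild type. The count of called genes between mutant and wild type fell to 1019 without wild type replicate 4 and to 1125 without wild type replicate 2. It fell to 1154 with only these 2 groups in the fit.

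Of 40 gene lists and cell type marker lists fixed before the data were examined, camera with a preset correlation of 0.01 called 17 between mutant and wild type, 9 higher and 8 lower. With an estimated correlation 1 call held, that of the integrated stress response, and fry, which tests a list's own direction without setting it against other genes, called 5 lists. These 5 were the integrated stress response, fatty acid oxidation, propionate catabolism with Mmut in it, endothelial and podocyte lists.

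The integrated stress response, the transcripts induced with the transcription factor Atf4, rose as a list (adjusted p = 1.44e-08 by camera, and adjusted p = 0.00269 with an estimated correlation). Of its 28 measured genes 9 rose and none fell, and 15 rose when adjusted over the list alone. Asns, which encodes asparagine synthetase, was 1.7-fold higher, Psat1 of serine synthesis 1.59-fold, the mitochondrial folate enzyme gene Mthfd2 1.47-fold and the transcription factor gene Atf5 1.28-fold. The call of Psat1 ended without any 1 of 9 arrays, with adjusted p up to 0.109.

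Among kidney injury and repair genes 8 of 30 rose and none fell, with 14 rising when adjusted over the list alone (camera adjusted p = 1.46e-06, adjusted p = 0.521 with an estimated correlation). Besides Lcn2 and Havcr1 these included the adhesion receptor gene Cd44, 1.48-fold higher, and the actin-binding protein gene Tmsb10, 1.39-fold higher. The call of Cd44 ended without any 1 of 10 arrays, with adjusted p up to 0.124. Fatty acid oxidation genes and targets of the nuclear receptor PPAR-alpha rose in 14 of 32 cases and fell in 1, or 18 and 1 when adjusted over the list alone (camera adjusted p = 6.16e-09, adjusted p = 0.521 with an estimated correlation). The acyl-CoA thioesterase gene Acot1 was 1.96-fold higher, the lipoprotein lipase inhibitor gene Angptl4 1.92-fold and Cyp4a14 1.68-fold. Angptl4 lost its call without any 1 of 5 arrays, with adjusted p up to 0.0961.

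Propionate, cobalamin and branched-chain amino acid catabolism, the pathways around the missing enzyme, fell as a list (camera adjusted p = 1.46e-06, adjusted p = 0.521 with an estimated correlation). Of 32 genes 13 fell, Mmut among them, and 1 rose, or 17 and 3 when adjusted over the list alone. The fall of Mmut is set by the genotype and the list was not tested without it, so its p-values partly restate the knockout. Mccc1, a subunit of an enzyme of leucine breakdown, was 1.5-fold lower, the branched-chain aminotransferase gene Bcat1 1.45-fold and the isovaleryl-CoA dehydrogenase gene Ivd 1.34-fold. The call of Bcat1 ended without any 1 of 7 arrays, with adjusted p up to 0.109. Cholesterol and lipid synthesis genes fell in 6 of 26 cases and rose in none, with 8 falling when adjusted over the list alone (camera adjusted p = 0.0207, adjusted p = 0.68 with an estimated correlation). Besides Scd1 these included Cyp51 of sterol synthesis, 2.31-fold lower, the fatty acid synthase gene Fasn, 1.71-fold lower, and the elongase gene Elovl6, 1.45-fold lower. The list was not called without mutant replicate 2 (adjusted p = 0.295), and Cyp51 was not called without wild type replicate 4 (adjusted p = 0.0528).

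Interferon response genes fell in 9 of 35 cases and rose in none, with 10 falling when adjusted over the list alone (camera adjusted p = 1.82e-05, adjusted p = 0.521 with an estimated correlation). The antiviral genes Ifit3 and Ifit1 were 1.73-fold and 1.71-fold lower, Rtp4 1.63-fold and the guanylate-binding protein gene Gbp3 1.55-fold. Without wild type replicate 2, Rtp4 was not called (adjusted p = 0.0616). Chemokines, cytokines and adhesion genes were called higher (camera adjusted p = 0.0055, adjusted p = 0.521 with an estimated correlation), although of 35 genes 2 rose and 2 fell, in both adjustments, over all genes and adjusted over the list alone. The risers were Tnf, 1.37-fold higher, and the nuclear factor kappa-B regulator gene Nfkbiz, 1.36-fold higher, while the chemokine genes Ccl28 and Cxcl14 fell. The calls of Tnf and Cxcl14 ended without any 1 of 3 and 9 arrays, with adjusted p up to 0.0695 and 0.0977.

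The p53 and DNA damage response list was also called higher (camera adjusted p = 0.00839, adjusted p = 0.68 with an estimated correlation), with 2 of 18 genes risen in both adjustments, over all genes and adjusted over the list alone. These were the growth arrest gene Gadd45a, 1.5-fold higher, and the death receptor gene Tnfrsf10b, 1.23-fold higher. Immediate early genes were called higher (camera adjusted p = 0.0185, adjusted p = 0.68 with an estimated correlation), with 2 of 23 risen and 3 when adjusted over the list alone. These were Myc, 1.84-fold higher, and Jund, 1.25-fold higher. Without mutant replicate 3 neither list was called (adjusted p = 0.0703 and 0.156), nor without wild type replicate 1 (adjusted p = 0.0536 for each).

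The mitochondrial lists were not called with all 12 arrays. Complex I of oxidative phosphorylation had 2 risen and 4 fallen genes of 34 (camera adjusted p = 0.208), led by Ndufc1, 1.36-fold lower, and complexes II to V had 4 risen and 2 fallen of 38 (camera adjusted p = 0.445), led by Atp5l, 1.49-fold higher. The tricarboxylic acid cycle had 1 risen and 3 fallen of 21 (camera adjusted p = 0.292), with the succinyl-CoA ligase subunit gene Sucla2 1.39-fold lower. Mitochondrial quality control and biogenesis had 2 risen and 4 fallen of 27 (camera adjusted p = 0.285). Only 2 mitochondrially encoded genes were measured and neither passed (camera adjusted p = 0.466). Antioxidant genes under the regulator NRF2 went both ways, with 3 risen and 3 fallen of 30 (camera adjusted p = 0.503). The quinone reductase gene Nqo1 was 1.6-fold higher and Gclm, of glutathione synthesis, 1.43-fold lower. Nqo1 was not called without wild type replicate 3 or 4, with adjusted p up to 0.0523. When adjusted over the list alone, the risen and fallen genes of complex I were 4 and 9, of complexes II to V 4 and 3, of the tricarboxylic acid cycle 1 and 3, of quality control 2 and 6, and of the antioxidant list 3 and 4. Without mutant replicate 1, camera called complex I, the tricarboxylic acid cycle and quality control lower (adjusted p = 0.00228, 0.0351 and 0.0494), and it called the tricarboxylic acid cycle lower after quantile normalization (adjusted p = 0.0153). With all 12 arrays these 3 lists had adjusted p = 0.834, 0.828 and 0.751 with an estimated correlation.

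A further 7 gene lists were not called with all 12 arrays. Extracellular matrix and fibrosis genes had 2 risen and 4 fallen of 37 (camera adjusted p = 0.832), with Mmp7, a matrix protease gene, 1.67-fold higher and the smooth muscle actin gene Acta2 1.5-fold lower. The cell cycle list had 1 risen and 2 fallen of 38 (camera adjusted p = 0.666), glycolysis 1 and 1 of 20 (camera adjusted p = 0.169), and gluconeogenesis, ammonia and acid-base genes 2 and 4 of 28 (camera adjusted p = 0.466). The renin, vitamin D, mineral and erythropoietin list had 1 risen and 3 fallen of 23 (camera adjusted p = 0.317). Its riser was Cyp27b1, the vitamin D activating hydroxylase gene, 2.65-fold higher, and the angiotensin-converting enzyme gene Ace was 1.82-fold lower. Circadian clock output had 2 risen and 1 fallen of 19 (camera adjusted p = 0.666), with the clock repressor gene Nr1d1 2.27-fold lower. In the complement and acute phase list, Lcn2 alone rose among 27 genes (camera adjusted p = 0.0681). When adjusted over the list alone, the risen and fallen genes numbered 2 and 5 for the matrix list, 1 and 2 for the cell cycle, 5 and 3 for glycolysis, 3 and 6 for the acid-base list, 1 and 3 for the renin list and 4 and 2 for the clock list, with 1 riser for complement. Camera called the complement list higher without mutant replicate 1, 3 or 4 (adjusted p = 0.00315, 0.0404 and 0.0377), with array weights (adjusted p = 0.0239) and with the replicate number as a block (adjusted p = 0.0476). With all 12 arrays the list had adjusted p = 0.719 with an estimated correlation. Camera called the matrix list higher without mutant replicate 1 (adjusted p = 0.0351) and glycolysis higher without mutant replicate 3 (adjusted p = 0.0404), and with all 12 arrays these had adjusted p = 0.959 and 0.68 with an estimated correlation.

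Markers of several kidney cell types were lower in mutants. Proximal tubule S3 markers fell in 6 of 11 cases (camera adjusted p = 0.00577, adjusted p = 0.521 with an estimated correlation), with Slc22a7 first, Serpina1f 1.6-fold lower and the aminoacylase gene Acy3 1.44-fold lower. Distal convoluted and connecting tubule markers fell in 5 of 9 (camera adjusted p = 0.000576, adjusted p = 0.521 with an estimated correlation), among them the sodium-calcium exchanger gene Slc8a1, 2.07-fold lower, the calcium-binding protein gene Calb1, 2.02-fold lower, the magnesium channel gene Trpm6, 1.43-fold lower, and the thiazide-sensitive cotransporter gene Slc12a3, 1.27-fold lower. Endothelial markers fell in 6 of 13 (camera adjusted p = 2.3e-06, adjusted p = 0.521 with an estimated correlation), with the sialomucin gene Emcn 1.53-fold lower and Ehd3 1.49-fold lower. Mutant replicate 3 stood apart in both the mean of this list (8.83, against 9.11 to 9.13 in the other mutants) and Emcn (10.20, against 10.85 to 10.90). Without that array the list was still called (median log2 fold change -0.20, adjusted p = 6.89e-05), as was Emcn (log2 fold change -0.45, adjusted p = 0.0106). Podocyte markers fell in 3 of 9 (camera adjusted p = 0.00307, adjusted p = 0.282 with an estimated correlation), namely Podxl, Nphs1 and Ptpro, 1.32-fold, 1.2-fold and 1.17-fold lower. Adjusted over the list alone, the falls numbered 6 with 1 rise for S3, and 7, 8 and 3 for the distal, endothelial and podocyte markers. Calls of Serpina1f, Slc8a1, Calb1 and Trpm6 ended without any 1 of 5, 4, 2 and 4 arrays (adjusted p up to 0.0719, 0.0738, 0.0568 and 0.0689), and that of Ptpro without wild type replicate 4 (adjusted p = 0.0524). The call of Nphs1 rests on the brighter of its 2 probe sets. The other went the opposite way (log2 fold change 0.08), and with their mean Nphs1 was not called (log2 fold change -0.10, adjusted p = 0.37).

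Proximal tubule transport and endocytosis genes fell in 9 of 43 cases and rose in none, or 12 and 3 when adjusted over the list alone (camera adjusted p = 0.0185, adjusted p = 0.715 with an estimated correlation). The organic anion and urate transporter family member Slc22a13 was 1.44-fold lower and the glucose transporter gene Slc5a1 1.3-fold lower. The list was not called without mutant replicate 3 (adjusted p = 0.287) or without wild type replicate 4 (adjusted p = 0.0604), and Slc22a13 was not called without wild type replicate 2 or 4, with adjusted p up to 0.0631. Markers of the first proximal tubule segments were not called as a list (camera adjusted p = 0.553), with 1 of 12 fallen in both adjustments, over all genes and adjusted over the list alone. It was Cubn, the endocytic receptor cubilin gene, 1.28-fold lower.

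Macrophage markers were called higher (camera adjusted p = 0.00307, adjusted p = 0.68 with an estimated correlation). Of 18 genes the lysozyme gene Lyz2 and Cd68 rose 2.4-fold and 1.57-fold, and the receptor gene Csf1r fell 1.55-fold, with the counts unaltered when adjusted over the list alone. The list was not called without mutant replicate 2 (adjusted p = 0.0511). Calls of Lyz2, Cd68 and Csf1r ended without any 1 of 5, 6 and 2 arrays (adjusted p up to 0.0847, 0.111 and 0.053). B and plasma cell markers were called higher with 1 of 11 risen in both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.00815, adjusted p = 0.68 with an estimated correlation). It was the coactivator gene Pou2af1, 1.35-fold higher, whose call ended without any 1 of 3 arrays (adjusted p up to 0.0745).

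Adrenal cortex markers, listed because the gland adjoins the kidney, were called higher (camera adjusted p = 0.0266, adjusted p = 0.697 with an estimated correlation), although none of 9 passed on its own, in either adjustment, over all genes or adjusted over the list alone. The call rested on mutant replicate 3, where all 9 were higher than on any other array. Cyp11b1, of corticosteroid synthesis, reached 12.65 there against a mean of 5.87 on the other 11 arrays, and Star, of steroid synthesis, reached 11.99 against 6.79. Without that array the list's median log2 fold change went from 1.02 to -0.015 (adjusted p = 0.938), and the call also ended without wild type replicate 1 (adjusted p = 0.0536). Mutant replicate 3 is 1 of the 4 mutants behind every comparison above, and without it 1553 genes were called. It also stood apart as the lowest mutant for Ace, Alb, Gbp3 and Slc22a13, at 9.47, 7.56, 7.41 and 10.54.

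The other marker lists were not called between mutant and wild type with all 12 arrays and the main test. Loop of Henle markers had 1 fallen of 10 (camera adjusted p = 0.0571), principal cells of the collecting duct 1 risen and 1 fallen of 11 (camera adjusted p = 0.97), intercalated cells 1 risen and 2 fallen of 11 (camera adjusted p = 0.666), fibroblasts and mural cells 2 fallen of 13 (camera adjusted p = 0.317), and hepatocytes 2 fallen of 10 (camera adjusted p = 0.832), which were Alb and Ttr. No marker passed among 16 of T and natural killer cells (camera adjusted p = 0.0876), 12 of neutrophils (camera adjusted p = 0.0571), 4 of blood (camera adjusted p = 0.0603) and 11 of perirenal fat (camera adjusted p = 0.0571), nor when adjusted over the list alone. The mean of the neutrophil markers was 6.91 in mutant replicate 2, against 5.83 to 6.01 in the other mutants. For the others the risen and fallen genes adjusted over the list alone numbered 0 and 4, 3 and 2, 3 and 2, 2 and 5, and 3 and 3, in the order given. For the hepatocyte list the median log2 fold change was 0.11 while its mean and the camera direction were below 0.

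Several of these marker lists lay close to the threshold and were called by camera with the preset correlation under some alternatives. With all 12 arrays, neutrophil, loop of Henle, fat, blood, and T and natural killer cell markers had adjusted p = 0.683, 0.613, 0.683, 0.68 and 0.683 with an estimated correlation. Neutrophil markers were called higher without mutant replicate 1, 3 or 4 or wild type replicate 3 (adjusted p = 0.0105, 0.0371, 0.0187 and 0.0249), with array weights (adjusted p = 0.0198), with centred medians (adjusted p = 0.0432) and with the block (adjusted p = 0.0357), but not without mutant replicate 2. Loop of Henle markers were called lower without mutant replicate 1, 2 or 4 or wild type replicate 2 (adjusted p = 0.0446, 0.0257, 0.0416 and 0.0388) and after quantile normalization (adjusted p = 0.0215), but not without mutant replicate 3. The mean of this list was 10.41 in that array, against 10.62 to 10.64 in the other mutants. Fat markers were called lower without mutant replicate 2 or wild type replicate 2 or 3 (adjusted p = 0.00486, 0.008 and 0.00704) and with the block (adjusted p = 0.0367). Blood markers were called higher without mutant replicate 3 or 4 (adjusted p = 0.00198 and 0.0319) and with array weights (adjusted p = 0.0116), and T and natural killer cell markers without mutant replicate 2 or wild type replicate 1 (adjusted p = 0.0353 and 0.0453).

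**Figure D3:**
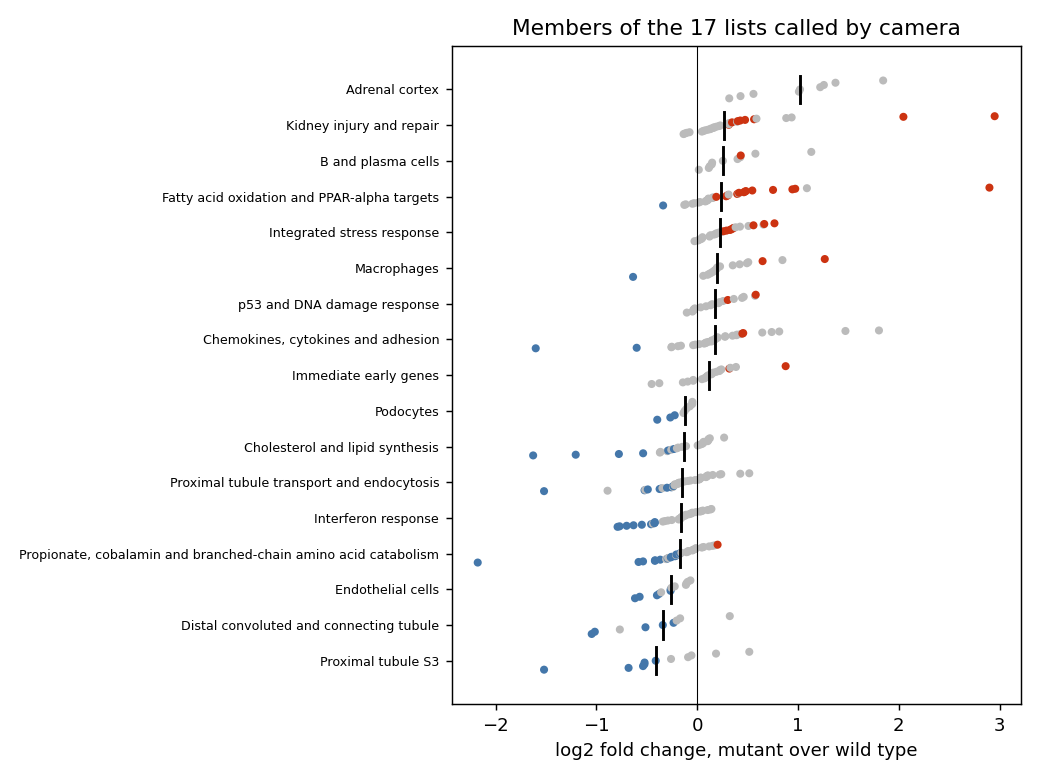
Log2 fold change, mutant over wild type, of each measured member of the 17 lists called by camera with the preset correlation, ordered by median (black line), with members that rose in red, fell in blue and did not pass in grey. Adrenal cortex markers have the highest median, 1.02, with no member that passed.

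Mutants were next compared with heterozygotes, which have an intact Mut allele. The fatty acid hydroxylase genes Cyp4a12b and Cyp4a12a were 4.65-fold and 3.93-fold higher in mutants, Lcn2 4.61-fold, Cyp27b1 2.64-fold and Npy6r 2.43-fold. Akr1c18 was 13.6-fold lower (log2 fold change -3.76, SE 0.38, adjusted p = 0.000372), Kap 5.58-fold, Igf2 5.04-fold, Alb 3.21-fold and Ttr 3.2-fold. Klk1b22, Fabp1 and Nat8f5, among the largest rises against wild type, did not pass between mutant and heterozygote (log2 fold changes -0.29, -0.16 and 0.30, adjusted p = 0.554, 0.939 and 0.679). Havcr1 did not pass either (log2 fold change 0.84, SE 0.56, adjusted p = 0.549, exact permutation p = 0.343), since heterozygotes held 6.25, 6.25, 8.86 and 8.70. The calls of Lcn2 and Cyp27b1 ended without any 1 of 7 and 5 arrays (adjusted p up to 0.0819 and 0.0693), and that of Npy6r without heterozygote replicate 2 (adjusted p = 0.0502). Over the alternatives the log2 fold change of Lcn2 ran from 1.82 to 2.81. With only these 2 groups in the fit Lcn2, Cyp27b1, Npy6r and Igf2 were not called (adjusted p = 0.123, 0.10, 0.0782 and 0.0668).

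In total 506 genes differed between mutant and heterozygote, 214 higher and 292 lower, and 99 of them by at least 1.5-fold. Leaving out a heterozygote array gave 235, 308, 248 and 229 genes for replicates 1 to 4, and a fit of these 2 groups alone gave 191. The excess of lower genes did not hold throughout, with 205 higher and 199 lower after centring of array medians, 100 and 91 in the fit of these 2 groups, and 121 and 114 without heterozygote replicate 1. Camera called 13 lists, 7 higher and 6 lower, of which 1, the integrated stress response, held with an estimated correlation (adjusted p = 0.000661). Of its 28 genes 5 rose, and 16 when adjusted over the list alone. Fatty acid oxidation genes rose in 8 of 32 cases, or 16 when adjusted over the list alone (camera adjusted p = 6.61e-12, adjusted p = 0.385 with an estimated correlation). Propionate and branched-chain amino acid catabolism, again with Mmut in the list, fell in 6 of 32, or 14 with 2 risers when adjusted over the list alone (camera adjusted p = 3.77e-06, adjusted p = 0.493 with an estimated correlation).

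The other lists called between mutant and heterozygote were those of injury, interferon, cell types and oxidative metabolism. Kidney injury genes rose in 2 of 30 cases, or 7 when adjusted over the list alone (camera adjusted p = 2.36e-08, adjusted p = 0.493 with an estimated correlation), and interferon response genes fell in 2 of 35, or 5 when adjusted over the list alone (camera adjusted p = 2.74e-06, adjusted p = 0.493 with an estimated correlation). Endothelial markers fell in 1 of 13 cases, podocyte markers in 2 of 9 and S3 markers in 3 of 11 (camera adjusted p = 6.49e-05, 0.00172 and 0.00621, and adjusted p = 0.493, 0.225 and 0.493 with an estimated correlation), or 5, 5 and 4 when adjusted over the list alone. Distal tubule markers had 1 risen and 2 fallen of 9, or 1 and 5 when adjusted over the list alone (camera adjusted p = 0.00196, adjusted p = 0.617 with an estimated correlation). The p53 list had 1 riser in both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.000288, adjusted p = 0.493 with an estimated correlation). Complexes II to V and the NRF2 antioxidant list were called higher here and were not called against wild type (camera adjusted p = 0.00135 and 0.00364, and adjusted p = 0.754 and 0.385 with an estimated correlation), with 2 risen, and 3 risen and 1 fallen. When adjusted over the list alone these were 2 risen, and 6 risen and 1 fallen. Adrenal cortex markers were called higher with none passing in either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00876, adjusted p = 0.754 with an estimated correlation), again with the values of mutant replicate 3.

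Few genes passed the threshold between heterozygotes and wild-type mice, although the 4 arrays of each group lay apart in 8.44% of genes. Klk1b22 was 31.9-fold higher (log2 fold change 4.99, SE 0.20, adjusted p = 1.79e-08), at 11.84 ± 0.32 against 6.84 ± 0.21 (SD, n = 4), and the related pseudogene Klk1b7-ps was 3.19-fold higher. Fabp1 was 7.79-fold higher, Nat8f5 3.35-fold and the amino acid transporter gene Slc6a15 1.98-fold. The brain-type fatty acid binding protein gene Fabp7 was 1.82-fold lower, Ggct of glutathione breakdown 1.74-fold, Mmut 1.53-fold, the cytokinesis motor gene Kif23 1.46-fold and the secreted inhibitor gene Chrdl1 1.43-fold. Lcn2 did not pass in the fit of all 3 groups (log2 fold change 0.74, SE 0.49, adjusted p = 0.593), whose shared spread includes the mutant SD of 1.43. Its heterozygote arrays, at 7.96 ± 0.25, nevertheless all lay above the wild-type arrays, at 7.21 ± 0.16 (SD, n = 4), with an exact permutation p of 0.0286, the smallest possible. With only these 2 groups in the fit its adjusted p was 0.0201, and over the other alternatives it ranged from 0.337 to 0.828. Havcr1 did not pass (log2 fold change 1.21, SE 0.56, adjusted p = 0.442, exact permutation p = 0.257). Slc6a15 was higher in heterozygotes than in wild-type mice and lower in mutants than in wild-type mice, with log2 fold changes of 0.98 and -0.64.

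In total 27 genes passed between heterozygote and wild type, 13 higher and 14 lower. Across fits that left out 1 array the count ranged from 5, without wild type replicate 4, to 67, without wild type replicate 1. With only these 2 groups in the fit it was 78, with array weights 163, with a trended and robust prior 42 and with the replicate number as a block 7. It was 55 without mutant replicate 3, and 8, 12 and 8 without heterozygote replicates 1, 2 and 4, and 7 and 6 without wild type replicates 2 and 3. In every fit that left out 1 array, 5 of the genes were called, namely Klk1b22, Klk1b7-ps, Mmut, the neuropeptide gene Npy and the receptor gene Vmn1r19. Npy and Vmn1r19 are outside the naming rule and were named after their values were seen. Calls of Fabp1, Nat8f5, Fabp7, Ggct, Kif23, Chrdl1 and Slc6a15 ended in some of those fits, with adjusted p up to 0.165, 0.115, 0.139, 0.0988, 0.139, 0.139 and 0.0988. Camera called 12 lists, 5 higher and 7 lower, while 0 were called with an estimated correlation and 0 by fry, where 0 and 3 lists had an unadjusted p under 0.05. Median log2 fold changes in the called lists were small, such as -0.07 for complex I of oxidative phosphorylation (camera adjusted p = 0.00106, adjusted p = 0.946 with an estimated correlation). The others called lower were cholesterol synthesis, endothelial, propionate, NRF2, fat and complexes II to V (camera adjusted p = 0.00711, 0.0285, 0.0286, 0.0309, 0.0309 and 0.0473). Those called higher were B and plasma cells, T and natural killer cells, immediate early genes, macrophages and chemokines (camera adjusted p = 1.77e-05, 0.0038, 0.00957, 0.0271 and 0.0309). Each of the 12 had adjusted p = 0.946 with an estimated correlation, and their only member that passed was Mmut. When adjusted over the list alone, 5 genes of complex I, 2 of complexes II to V, 1 of propionate and 1 of NRF2 fell, and 1 gene each of propionate, T and natural killer cells, and B and plasma cells rose.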

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

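In this part the test of a change shared by the mutant genotype was chosen after the result was seen, and the test with adrenal medulla markers was written before its result. Each array was compared with the others of its group by the gap to its nearest neighbour as a share of the range, and 22 of 363 sets of a named gene and a group, and 10 of 120 sets of a list and a group, held an array apart. Chance gives about 1 in 20 such sets. The arrays apart are therefore given as values, and only the pattern in mutant replicate 3 is weighed.

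In mutant replicate 3 the genes apart were Ace (9.47), Alb (7.56), Emcn (10.20), Gbp3 (7.41), Hsd3b1 (8.06, against 4.23 to 4.51 in the other mutants), Slc22a13 (10.54) and Slc26a4 (8.72). List means apart there were those of the loop of Henle (10.41), endothelial cells (8.83) and the adrenal cortex (10.19, against 6.13 to 6.18). In mutant replicate 2 they were Acta2 (9.60), Tnfrsf10b (7.57) and the neutrophil list (6.91), in mutant replicate 1 Rrm1 (8.38) and in mutant replicate 4 Ptpro (7.89). Among heterozygotes they were Atp6v0d2 (9.76) and Serpina1f (11.16) in replicate 1, the p53 list (8.14) in replicate 2, Myc (7.57) and Ttr (9.55) in replicate 3, and Tnf (6.27) and the complement list (7.35) in replicate 4. Among wild-type mice they were Cd5 (6.90) and Slc8a1 (9.71) in replicate 1, Nr1d1 (10.65) and the fatty acid oxidation list (10.51) in replicate 2, Cbr3 (6.31) in replicate 4, and in replicate 3 Cyp4a12b (6.32), Slc22a7 (9.99) and the cell cycle (7.04), renin (9.79) and distal tubule (10.63) lists.

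All 9 measured adrenal cortex markers were highest in mutant replicate 3, by a median of 3.72 on the log2 scale over the mean of the other 11 arrays. Bootstrap SDs here and below resample the genes of a list, so they do not measure the spread between mice. The rise was not shared by the other mutants, as the median log2 fold change without mutant replicate 3 was -0.015 (bootstrap SD 0.0565). Adrenal tissue in that sample may be the source, and 5 of 9 medulla markers were also highest there, with Dbh, Pnmt and Scg2 higher by 1.10, 1.32 and 1.28, while Cartpt and Slc18a2 were higher by 0.18 and 0.09 and Slc18a1 differed by -1.03. The medulla median, 0.296, nevertheless lay just under the bound of 0.3 set against this explanation, by less than its bootstrap SD of 0.328, so that test left it open. Ddc, Npy and Slc18a1 had means of 9.71, 8.70 and 10.70 on the other 11 arrays, which could hide a small share of medulla. The lower level of Slc18a1 is not itself explained by a high baseline, but with such a baseline it says little about medulla.

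Of the 13767 probe sets outside the gene tests, which have several gene symbols or none, 895 were called by limma between mutant and wild type, 547 higher and 348 lower. Between heterozygote and wild type limma called 0, with 1256 at an unadjusted p under 0.05. Among the 895 were 279 with several genes, and the genes behind the others were not analysed here.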

How the results depend on the processing

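The fit without the genes over 2-fold higher in mutant replicate 3 than on any other array was chosen after the result was seen, and gave 1938 genes between mutant and wild type, 508 between mutant and heterozygote, 27 between heterozygote and wild type, and 16 lists. The other alternatives in this part were chosen before.

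Leaving out 1 array gave 1019 to 1928 genes for mutant against wild type, 229 to 592 for mutant against heterozygote and 5 to 67 for heterozygote against wild type. With only the groups compared in the fit the counts were 1154, 191 and 78, and with the 1.5-fold threshold 207, 99 and 13. Heterozygote against wild type gave 7 with the replicate number as a block, 163 with array weights and 42 with a trended and robust prior. The block gave 1552 and 405 for the other comparisons, and pooled controls 1634. Of 12 pairs of arrays with the same replicate number 1 correlated above 0.1, with a median r of 0.00951, so the numbers were not treated as pairs. Mutant replicate 3 had the lowest array weight, 0.386.

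The share of called genes that were higher in mutants than in heterozygotes was 42.3%, and 50.7% after centring of medians, 36.4% after quantile normalization, 52.4% with only these groups in the fit and 51.5% without heterozygote replicate 1. Which direction held more genes thus depended on the centring, on the groups in the fit and on 1 array. For mutant against wild type that share ranged from 26.6% to 39.1%. For heterozygote against wild type it was 48.1%, and it turned both ways, from 22.4% without wild type replicate 1 and 29.4% with array weights to 57.1% with the block and 66.7% without wild type replicate 3.

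Lists called between mutant and wild type numbered 17, from 15 to 24 when leaving out 1 array, 1 with camera with an estimated correlation and 5 with fry. With genes with a group mean of at least 6 only, proximal tubule transport, cholesterol synthesis and the adrenal cortex were not called (adjusted p = 0.0545, 0.0653 and 0.0743), nor were transport and the adrenal cortex with array weights (adjusted p = 0.0588 and 0.0935). The uncalled lists turned direction most. Camera's direction for collecting duct principal cells turned with a replicate block and with genes with a group mean of at least 6 only (median -0.0476 in each), with array weights (-0.0336) and with quantile normalization (-0.0384). It also turned for hepatocytes with the block (0.113), for complexes II to V with quantile normalization (-0.00984), for the extracellular matrix with only the 2 groups and with fry (-0.00761 in each) and for intercalated cells with fry (0.0402). Leaving out 1 array gave medians of -0.0247 to 0.0552 for complexes II to V, -0.0414 to 0.0606 for the matrix, -0.0303 to 0.0542 for the cell cycle, -0.0660 to 0.0459 for the clock, -0.0807 to 0.00635 for S1 and S2, -0.0787 to -0.00583 for principal cells, 0.0334 to 0.212 for hepatocytes and -0.0152 to 1.38 for the adrenal cortex.

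Of 130 called results of named genes, all 130 kept their direction under each setting run for them, and 74 were called under each of these but the fold threshold. Pooled controls were run for 109 of them and the filter on group means for 129. The fold threshold ended 61 calls, leaving out wild type replicate 4, 2 or 3 ended 46, 38 and 34, and a fit of only the 2 groups ended 34.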

Other observations

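In this part the tests of linked chromosome segments, of Mut dose, of mRNAs with a 5' terminal oligopyrimidine tract, of shared wild-type arrays and of male-biased genes were chosen after the result was seen, as were the families of ribosomal protein genes and small nucleolar RNAs themselves. The splits of the arrays, the trend with signal level and the test of a single mutant array were written before.

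Whether chance gives such counts was tested by splitting the 8 arrays of each comparison in all 35 ways. For mutant against wild type the real split gave 1925 genes and the highest other 2, for mutant against heterozygote 506 and 10, and for heterozygote against wild type 27 and 0. In each comparison 1 split, the real one, gave as many genes by limma, which is the smallest share that 35 splits allow. The other splits mix the groups, so a real difference adds to their spread and lowers their counts. They therefore do not exclude chance. At an unadjusted p under 0.05 the real splits gave 4867, 3072 and 2255 genes and the highest others 3539, 1980 and 1905. The sample numbers run group by group, so an effect of processing order stays open for all of these counts.

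Ribosomal protein genes, a family picked from these data and so given no p, were higher in mutants than in wild-type mice, with 45 of 61 risen, 0 fallen and a median log2 fold change of 0.38 (0.37 after centring of medians and after quantile normalization). Genes of like signal level did not share the rise, since 10000 random lists matched on mean level had medians centred on -0.046, with the highest at 0.0393. As the family was picked from these data, the 0% of lists with a median as high is no measure of chance. All 4 mutant arrays lay above the wild-type mean by more than 0.1 (0.40, 0.37, 0.43 and 0.32), so the rise was not that of a single array. The calls of its members already implied much of this. A change of the wider class of mRNAs with a 5' terminal oligopyrimidine tract may be the reason, as 15 listed members that encode no ribosomal protein had a median of 0.246 (bootstrap SD 0.0449), but this was tested on the same data and processing order stays open. Small nucleolar and Cajal body RNAs, which are not mRNAs, also moved up, with 21 of 54 risen, 0 fallen and a median of 0.22 (0.21 after centring and 0.22 after quantile normalization). Whether some of them are cut from transcripts of that class was not examined, so their rise is not weighed for or against it.

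For the 27 genes called between heterozygote and wild type, linked chromosome segments that differ between the mice stay open. Of these genes 9 lay within 100 genes of another called gene of another family. Random lists had a median of 6, and at most 10 in all but about 1 in 20 of them (permutation p = 0.155). The count ignores how many called genes share a stretch and leaves out pairs of 1 family, so it could miss such segments. Among the 9, all named here for their position, were Sucla2 and Tnfrsf10b, named in lists above. Their log2 fold changes from wild type were -0.33 and 0.31 in heterozygotes and -0.48 and 0.30 in mutants. In heterozygotes Rhobtb2, Cysltr2, Npy, Ggct and Fabp1 moved by -0.47, -0.45, 0.87, -0.80 and 2.96. In mutants the same genes moved by -0.51, -0.48, 0.81, -0.86 and 2.80. Phyhip and Vmn1r19 moved further in mutants, by -0.67 and -2.28 against -0.32 and -1.39 in heterozygotes. A linked segment was thus not separated from genotype for any of the 9. Of the other called genes 0 lay within 100 genes of Mmut. The dose of the Mut allele stays open as well, since the mutant mean lay further from wild type in 62.5% of 40 gene tests that used heterozygote arrays which had not chosen the gene. These tests count the same few genes repeatedly over overlapping pairs of arrays, and pairs that chose genes with heterozygote replicate 1 gave 8 of 10, 7 of 9 and 8 of 12, while the others gave 0 of 3, 2 of 4 and 0 of 2. Across genes, heterozygotes lay on the mutant side of wild type. With disjoint wild-type arrays, none shared by both comparisons, the lowest covariance of the fold changes over 6 splits was still 0.0111. In 100 simulations without effects it was at most 0.000583, but these drew each gene independently. Real arrays can vary in many genes together, and the 6 splits reuse the same arrays, so the simulations do not show what chance gives. Sharing of arrays was thus not needed for the covariance, while chance was not excluded. The difference may follow Mut dose, litter or processing order, which these arrays do not separate.

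The rise of Cyp4a12b and Cyp4a12a raised the question of male-type expression in mutant kidneys. Of 13 other genes known to be higher in male kidneys 1 rose, Cyp2j13, and 1 fell, Serpina1f, with a median log2 fold change of -0.00777 (bootstrap SD 0.121). Members went both ways, so the test left the question open. Kap, the androgen-regulated gene, was not in that list and fell by 2.65 on the log2 scale. It is 1 gene named for its large fall, so it does not settle the question either.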
